A study of Oryza sativa with 4 samples.

How the data were processed

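Panicles of the rice cultivar Dongjin at inflorescence stage 7 (0.3 to 1.5 cm long) were compared between wild type and emf2b, with 2 libraries of each. Plants grew in a greenhouse at 30°C by day and 25°C by night. Per the labels' protocols, total RNA was treated with DNase, 10 ng were amplified to cDNA with the Ovation RNA-seq system, and 40 cycles of single reads were run on an Illumina Genome Analyzer IIx. The protocol text of all 4 samples speaks of tissue from wild-type plants, also for the emf2b samples; groups were taken from the genotype label. The emf2b allele is not given in the sources used here.

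The deposited table holds whole-number read counts per gene model, not normalized, for 45027 loci with identifiers of the MSU rice annotation type, and each of these has at least 1 read in some library. TopHat2 2.0.5 and DESeq 1.10.1 are named in the submitters' processing notes. The read counter, genome build, annotation release and use of strand are not given in the sources used here, so overlapping or antisense genes and near-identical copies cannot be resolved. Totals were 12932305 and 16926873 counts in the emf2b libraries and 25382519 and 32087683 in the WT libraries. A floor of 3 reads corresponds to 0.232, 0.177, 0.118 and 0.0935 CPM in emf2b GAGT, emf2b TTAG, WT ACCC and WT CGTA. Exact 95% intervals of read ratios and floors cover counting error only. The columns name the genotype and a 4-base barcode but no replicate number, so a column was assigned to its group and not to a numbered sample. Libraries of 1 group differed far beyond the noise of counting reads (chi-square per degree of freedom 46.5 for the emf2b pair and 57.7 for the WT pair). This spread may be technical and does not show that they are biological replicates. Each library was counted as 1 replicate. Spearman correlations across loci were 0.963 within emf2b, 0.985 within WT and 0.930 to 0.939 between the groups; loci are not independent replicates.

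Loci were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15) in R 4.3.3, leaving 22615. Libraries were scaled by TMM, with factors of 0.996, 1.03, 0.973 and 1.00 for emf2b GAGT, emf2b TTAG, WT ACCC and WT CGTA. The edgeR quasi-likelihood F test was used on the counts (group as the only term, 2 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change is higher in emf2b. The standard error is the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 26.0%. CPM (counts-per-million) values used the library total, without the TMM factor, given as mean ± SD of 2 libraries.

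Before the data were examined, 13 gene lists, the rule for named genes, the test and the main alternatives were fixed. The lists were PRC2 and associated factors, floral organ identity genes, E-class and AGL6-clade MADS genes, other MADS-box genes, flowering time and clock genes, meristem and spikelet genes, seed genes, anther and tapetum genes, meiosis genes, photosynthesis genes, cell cycle genes, stress and defence genes, and reference genes. They hold 186 loci, of which 181 are in the table and 130 were tested. Named genes were all of the PRC2 and floral lists, up to 4 called members of each other list (or 2 uncalled members with the largest change), and the 2 higher and 2 lower loci with the largest change among calls whose libraries did not overlap between the groups. Genes outside this rule are said to be so where they appear. List tests used camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation, and fry, each adjusted over the 13 lists.

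The table does not pair identifiers with gene names. Names were taken from general knowledge of rice loci, written with their identifiers before the data were examined, and then checked against a RefSeq gene table of assembly ASM3414082v1, another build, from which no coordinates were used. Of 201 symbols, including those of 3 lists added later, 132 occurred there on the chromosome given by the locus identifier, 8 only on another chromosome, 2 more than once and 59 not at all. Of 857 pairs of such genes on the same chromosome, 855 were in the same order. EMF2B, FIE1, FIE2, WRKY45 and UBQ10 were among those not found, and MFS1 and DMC1B among those whose symbol belongs to a locus on another chromosome there, so these names rest on the prior list alone.

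On simulated counts for the 22615 tested loci, with the real library sizes and 200 loci changed, the same test called 3 of 50 loci changed 2-fold, 32 of 50 changed 4-fold, 39 of 50 changed 8-fold and 48 of 50 changed 16-fold. Unchanged loci made up 6.87% of the calls, 1 of 100 random lists passed camera at an unadjusted p under 0.05, and 0 chromosomes passed. No background reads were simulated. Loci were drawn independently, so the list and chromosome results do not cover genes that vary together. The real comparison had 3556 calls and so a looser cutoff of unadjusted p, and these shares need not hold for it.

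Alternatives fixed in advance were RLE size factors, no scaling beyond library totals, DESeq2 1.42.0, no low-count filter, a stricter filter (above 1 CPM in 2 libraries and a mean count of 20), legacy and robust dispersion estimates, other thresholds, and leaving out each library. Chosen after seeing the data were a filter at a mean of 5 CPM, thinning all libraries to the depth of the shallowest, and lowering emf2b counts by the 95th or 99th percentile of that library's counts at loci with no WT read, which are 5 and 11 (95th) and 10 and 22 reads (99th) for GAGT and TTAG. Calls per chromosome were compared by two-sided Fisher's exact tests over 12 chromosomes. For DESeq2, list and chromosome totals include every locus with a fold change. Of these 45027 loci, 18328 had no adjusted p and could not be called.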

Results

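Transcript levels were measured by RNA-seq in young panicles of the rice cultivar Dongjin, from wild-type (WT) plants and from plants mutant in EMF2B, a gene for a subunit of Polycomb repressive complex 2 (PRC2). This complex places the repressive mark H3K27me3 on chromatin. Panicles were at inflorescence stage 7 and 0.3 to 1.5 cm long, and each genotype had 2 libraries. The 2 WT libraries, ACCC and CGTA by their sequence barcodes, held 25382519 and 32087683 counted reads. The 2 emf2b libraries, GAGT and TTAG, held 12932305 and 16926873, so the mutant was sequenced less deeply. The question was which transcripts differ when EMF2B is mutated, in a series whose title ties the gene to flower meristem determinacy and the specification of floral organs.

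EMF2B itself (LOC_Os09g13630, chromosome 9) fell in the mutant. It stood at 9.90 and 11.9 counts-per-million (CPM) in the emf2b libraries GAGT and TTAG, and at 37.1 and 38.8 CPM in the WT libraries ACCC and CGTA. The group means were 10.9 ± 1.40 CPM in emf2b and 37.9 ± 1.17 CPM in WT (SD, n = 2 each), a log2 fold change of -1.83 ± 0.21 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00661). Reads at the locus were therefore reduced and not lost, from 942 and 1244 reads in WT to 128 and 201 in emf2b. Among the 10 measured genes of PRC2 and its associated factors, 1 rose, 1 fell and 8 did not pass the test, the same counts as when adjusted over the list alone. The gene that rose was FIE1 (LOC_Os08g04290, chromosome 8), a copy of the WD40 subunit of PRC2 known from endosperm. It had 10 and 18 reads in the emf2b libraries and 1 and 0 in WT, a depth-adjusted ratio of 53.9 with a 95% exact interval of 8.91 to 2204 (edgeR adjusted p = 0.0163). FIE2, its neighbour and paralog, stood at 23.2 ± 1.38 CPM in emf2b and 24.7 ± 4.53 CPM in WT (SD, n = 2 each), and short reads of the pair could have been shared by the counting. The paralog EMF2A had a log2 fold change of -0.28 ± 0.19 (SE). The histone methyltransferase genes CLF and iEZ1 had -0.37 ± 0.19 and -0.17 ± 0.24, and LHP1, whose protein binds H3K27me3, had -0.50 ± 0.17, none of them past the test. The PRC2 list as a set did not pass camera (adjusted p = 0.148). Its median log2 fold change was -0.24 (-0.37 without WT ACCC) and its camera direction was down, while its mean, FIE1 included, was 0.15. The EMF2B call ended when either WT library was left out, as did nearly all calls of the whole comparison. Those fits leave 1 residual degree of freedom. With 1 library left out, the log2 fold change of EMF2B stayed between -1.95 and -1.73. The FIE1 call also ended without either WT library. It ended too when emf2b counts were lowered by the level found at loci with no WT read (log2 fold change 5.31 before, 4.20 ± 1.42 SE at the 95th percentile and -1.98 ± 3.75 at the 99th). The 99th percentile, 10 reads in GAGT and 22 in TTAG, takes away all emf2b reads of FIE1, so that value cannot test the call.

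Floral organ identity genes showed some of the deepest losses of reads among the named genes. OsMADS8, an E-class (SEPALLATA-like) gene, fell from 18.6 ± 8.64 CPM in WT to 1.23 ± 0.23 CPM in emf2b (SD, n = 2 each; log2 fold change -3.97 ± 0.45 SE, edgeR adjusted p = 0.00679). OsMADS6, an AGL6-clade gene with roles in floral meristem and organ identity, fell from 170.3 ± 57.7 to 20.3 ± 3.16 CPM (-3.10 ± 0.27, edgeR adjusted p = 0.00489). OsMADS1, an E-class gene needed for lemma and palea identity, fell from 27.1 ± 6.06 to 7.55 ± 1.24 CPM (-1.88 ± 0.27, edgeR adjusted p = 0.00909). OsMADS16, a B-class gene of lodicules and stamens, fell from 7.53 ± 3.06 to 1.39 ± 1.20 CPM (-2.40 ± 0.57, edgeR adjusted p = 0.0302). DROOPING LEAF (DL), a YABBY gene that specifies the carpel, fell from 4.33 ± 0.49 to 1.37 ± 0.07 CPM (-1.69 ± 0.40, edgeR adjusted p = 0.03004). In the other direction, OsMADS21, of the lineage that includes ovule identity genes, had 24 and 34 reads in the emf2b libraries and 0 and 6 in WT (4.12 ± 0.82, edgeR adjusted p = 0.0169). Its log2 fold change ran from 3.15 to 8.13 under the alternative settings.

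Of 20 floral organ identity genes, 18 were tested. Of these 1 rose, 5 fell and 12 did not pass the test, and 3 rose and 6 fell when adjusted over the list alone. OsMADS4, a B-class gene, was at 2.43 ± 1.59 CPM in WT and 0.60 ± 0.02 CPM in emf2b (SD, n = 2 each; edgeR adjusted p = 0.0927). OsMADS34, an E-class gene that acts in panicle branching, was at 13.2 ± 2.17 and 29.8 ± 13.4 CPM (edgeR adjusted p = 0.0644), and was called higher with DESeq2 and without emf2b TTAG (edgeR adjusted p = 0.0105). The APETALA1-like genes OsMADS14 and OsMADS15 had log2 fold changes of 0.54 ± 0.18 and 0.27 ± 0.19 (SE), and the C-class genes OsMADS3 and OsMADS58 had -0.60 ± 0.56 and 1.43 ± 0.71. The remaining 6 tested members had log2 fold changes from -0.57 to 0.32. OsMADS13 and OsMADS20 were too weakly counted to be tested. Of the 7 E-class and AGL6-clade genes, OsMADS1, OsMADS6 and OsMADS8 fell and 4 did not pass the test, with 1 higher and 3 lower when adjusted over the list alone. As sets, neither the floral list (median log2 fold change -0.43) nor the E-class and AGL6 list (-0.42) passed camera, each at an adjusted p of 0.0615. The medians were -0.04 and -0.06 without WT CGTA, and -0.72 and -0.75 without WT ACCC; that of the E-class and AGL6 list was -1.01 without emf2b GAGT. The libraries of 1 group also differed at these genes: OsMADS6 was at 129.6 CPM in WT ACCC and 211 CPM in WT CGTA, and OsMADS8 at 12.5 and 24.7 CPM. The OsMADS16 and DL calls ended without emf2b GAGT and with a stricter low-count filter, the DL call also without emf2b TTAG, and the OsMADS21 call after emf2b counts were lowered by the level at loci with no WT read (log2 fold change 3.15 at the 99th percentile), as did that of OsMADS16 with a larger change (-3.68). Leaving out WT CGTA ended every call of this list, and leaving out WT ACCC ended every call except that of OsMADS6. Nearly all calls of the whole comparison ended in these fits, so the loss is not particular to this list.

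**Figure D1:**
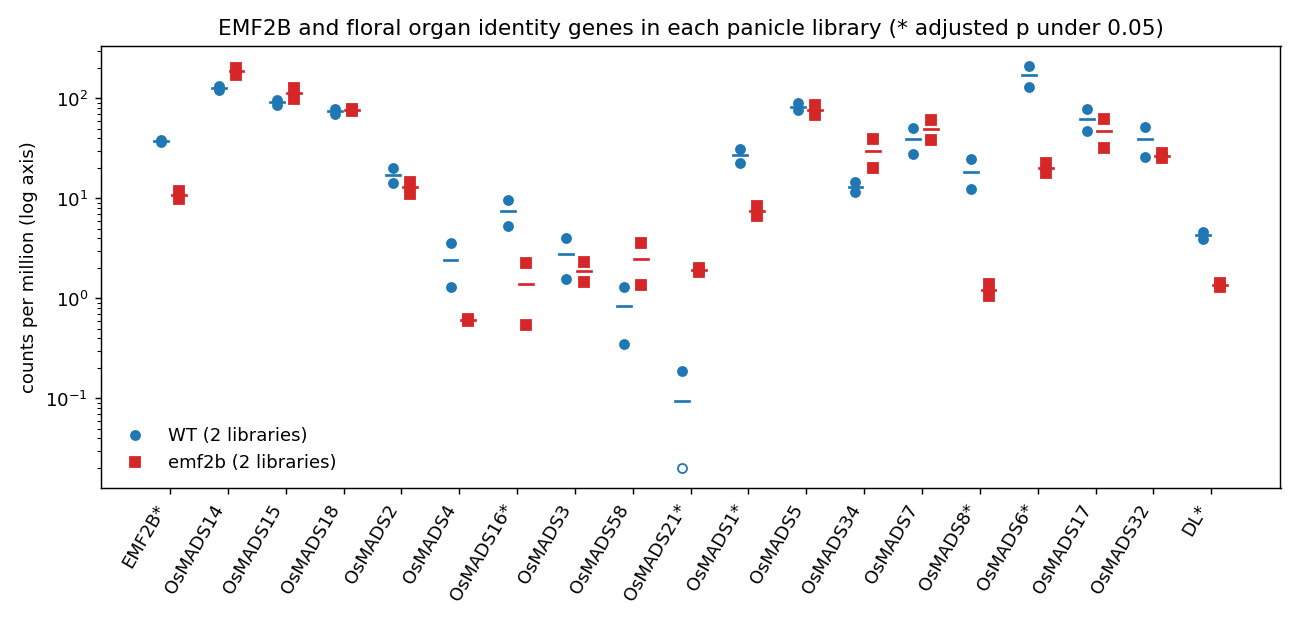
Counts-per-million (log axis) of EMF2B and of the 18 tested floral organ identity genes in each library; circles are the 2 WT libraries, squares the 2 emf2b libraries, horizontal bars the group means, the open circle 1 library with 0 reads drawn at the foot of the axis, and an asterisk marks an edgeR adjusted p under 0.05. OsMADS6 and OsMADS8 show the widest gaps downward in emf2b, at means of 20.3 and 1.23 CPM against 170.3 and 18.6 CPM in WT.

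Of the SVP-like MADS-box genes OsMADS22, OsMADS47 and OsMADS55, known as repressors of floral meristem identity and in brassinosteroid responses, 2 rose. OsMADS22 rose from 9.62 ± 2.35 CPM in WT to 32.2 ± 11.6 CPM in emf2b (SD, n = 2 each; log2 fold change 1.71 ± 0.32 SE, edgeR adjusted p = 0.0152). OsMADS47 rose from 0.27 ± 0.07 to 2.08 ± 1.08 CPM (2.96 ± 0.64, edgeR adjusted p = 0.0227). OsMADS55, named after its value was seen, was at 5.66 ± 0.91 CPM in WT and 2.68 ± 0.03 CPM in emf2b (-1.11 ± 0.36, edgeR adjusted p = 0.0799). OsMADS22 and OsMADS47 were the only calls among the 12 tested members of the other MADS-box genes (0 fell, 10 did not pass); adjusted over the list alone, 2 rose and 3 fell, and DESeq2 called 2 higher and 2 lower of 23. The set did not pass camera (adjusted p = 0.705, direction down). Its mean log2 fold change was 0.26 and its median 0.12, a median of no stable sign (-0.14 to 0.26 with 1 library left out, and -0.45 over the 5 members with a mean of 5 CPM or more). Among flowering time and clock genes, RID1, a zinc finger gene needed for the switch to flowering, rose from 0.09 ± 0.04 to 1.50 ± 1.14 CPM (4.04 ± 0.88, edgeR adjusted p = 0.0203). It was the only call among 13 tested members, with 0 lower and 12 not past the test; 2 were called higher under RLE factors or library totals alone, and 1 higher and 2 lower of 18 with DESeq2. The list had 2 higher and 2 lower when adjusted over the list alone, a median of 0.19 (0.07 to 0.30 with 1 library left out) and a camera adjusted p of 0.658. The calls of OsMADS47 and RID1 ended without emf2b TTAG and when emf2b counts were lowered by the level at loci with no WT read, that of RID1 also after thinning to equal depth; lowering by the 95th percentile left log2 fold changes of 2.67 ± 0.74 and 3.57 ± 1.05 (SE). The OsMADS22 call ended when only loci with a mean of 5 CPM or more were tested.

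Among meristem and spikelet genes, STAMENLESS1 (SL1), a zinc finger gene that promotes B-class gene expression, fell from 88.9 ± 20.9 CPM in WT to 20.7 ± 3.95 CPM in emf2b (SD, n = 2 each; log2 fold change -2.14 ± 0.23 SE, edgeR adjusted p = 0.00650). OsYABBY3 fell from 10.4 ± 3.97 to 4.12 ± 0.36 CPM (-1.36 ± 0.36, edgeR adjusted p = 0.0415). MFS1, an ERF gene of spikelet meristem fate, rose from 113 ± 1.63 to 385 ± 226 CPM (1.75 ± 0.39, edgeR adjusted p = 0.0237), with 545 CPM in emf2b GAGT and 226 CPM in emf2b TTAG. Of the 13 tested members, 1 rose, 2 fell and 10 did not pass the test, and 1 rose and 3 fell when adjusted over the list alone. The set did not pass camera (adjusted p = 0.550, direction down), with a median of 0.03 (-0.17 to 0.05 with 1 library left out) and a mean of -0.06. The OsYABBY3 call ended without either emf2b library, with scaling by library totals alone, with both higher count filters and after thinning. The MFS1 call ended with robust dispersion estimates and with a filter at a mean of 5 CPM; lowering emf2b counts by the 99th percentile ended both calls but left log2 fold changes of -1.61 and 1.91.

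Of 14 meiosis genes, 5 fell in emf2b. MEL1, an Argonaute gene of germ cells, fell from 90.2 ± 8.73 CPM in WT to 14.1 ± 0.79 CPM in emf2b (SD, n = 2 each; log2 fold change -2.71 ± 0.19 SE, edgeR adjusted p = 0.00298). ZEP1, for the central element of the synaptonemal complex, fell from 97.9 ± 0.36 to 17.71 ± 3.16 CPM (-2.50 ± 0.21, edgeR adjusted p = 0.00489). PAIR2, for a protein of the chromosome axis, fell from 78.0 ± 22.7 to 37.0 ± 2.61 CPM (-1.11 ± 0.23, edgeR adjusted p = 0.0193). DMC1B, for a meiotic recombinase, fell from 15.2 ± 6.71 to 4.19 ± 2.17 CPM (-1.91 ± 0.47, edgeR adjusted p = 0.0338), although its reads could be shared with the near-identical DMC1A. PAIR3, another axis gene named here only after its value was seen, fell from 17.3 ± 3.78 to 6.75 ± 3.74 CPM (-1.38 ± 0.38, edgeR adjusted p = 0.0487).

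All 14 meiosis genes were tested and all had negative log2 fold changes. Of these 5 fell, 0 rose and 9 did not pass the test, and the counts adjusted over the list alone were the same; 3 fell without emf2b GAGT and with the stricter filter, and 2 at a mean of 5 CPM. The list was lower as a set by camera with the preset correlation of 0.01 (median log2 fold change -0.78, or -1.34 without emf2b TTAG; adjusted p = 0.000127). That call was lost with an estimated correlation of 0.042 (camera p = 0.0634, adjusted p = 0.742). In that version camera uses the 2 residual degrees of freedom, at which no list passed. The loss therefore does not show that correlation between genes undid the call. Among 8 tested cell cycle genes, 0 rose and 0 fell, also when adjusted over the list alone, although 2 were called lower without emf2b TTAG. The median was -0.69 (-0.97 to -0.42 with 1 library left out) and the camera adjusted p was 0.0726. The cyclin gene CYCB2-2 was at 55.1 ± 18.7 CPM in WT and 30.7 ± 16.6 CPM in emf2b (SD, n = 2 each; edgeR adjusted p = 0.175, and 0.0233 without emf2b TTAG), and KRP1, an inhibitor of cyclin-dependent kinases, at 0.57 ± 0.08 and 1.26 ± 0.47 CPM (edgeR adjusted p = 0.232). Among 6 tested anther and tapetum genes, 0 rose and 0 fell, while 1 rose and 1 fell when adjusted over the list alone. The tapetum bHLH genes EAT1 and TIP2 were at 1.01 ± 0.58 and 0.69 ± 0.53 CPM in WT and at 4.81 ± 4.06 and 2.26 ± 0.14 CPM in emf2b (edgeR adjusted p = 0.0717 and 0.112), and EAT1 was called higher with DESeq2 and without emf2b GAGT (edgeR adjusted p = 0.0131). The anther set did not pass camera (adjusted p = 0.705, direction down), with a median of 0.02 (-0.08 to 0.10 with 1 library left out) and a mean of 0.30. Without emf2b GAGT the PAIR2 and PAIR3 calls ended, and without emf2b TTAG the DMC1B call ended. Without either WT library every meiosis call ended, as did nearly all calls of the whole comparison. The PAIR2, DMC1B and PAIR3 calls also ended with a filter at a mean of 5 CPM and after lowering of emf2b counts by the 99th percentile (log2 fold changes then -0.97, -2.19 and -1.42), those of DMC1B and PAIR3 with the stricter filter, and that of PAIR3 with library totals alone, with legacy dispersions and after thinning.

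A dehydrin gene and a regulator from the seed list rose in emf2b, each unequally in its 2 libraries. RAB16A, a dehydrin gene induced by abscisic acid (ABA), had 798 CPM in emf2b GAGT, 78.2 CPM in emf2b TTAG, and 10.4 and 10.3 CPM in WT (log2 fold change 5.39 ± 0.998 SE, edgeR adjusted p = 0.0150). Its reads could be shared with other RAB16 genes of the same cluster. VP1, a B3-domain regulator of seed maturation, rose from 0.13 ± 0.05 CPM in WT to 1.88 ± 1.68 CPM in emf2b (SD, n = 2 each; 3.91 ± 0.91, edgeR adjusted p = 0.0266). Of 11 tested seed genes, 2 rose, 0 fell and 9 did not pass the test, and 6 rose and 0 fell when adjusted over the list alone. Under RLE factors or library totals alone 4 were called higher, and 1 with the stricter filter or robust dispersions. The list was higher as a set by camera (median 2.02, adjusted p = 0.0202). With an estimated correlation of 0.059 that call was lost (camera p = 0.133, adjusted p = 0.742), again on 2 residual degrees of freedom. The median was 0.34 with the stricter filter, at which 6 members were tested, and 0.38 after lowering emf2b counts by the 99th percentile. The VP1 call ended without emf2b TTAG and after lowering emf2b counts by the level at loci with no WT read, with log2 fold changes of 3.59 ± 1.08 (95th percentile) and 3.10 ± 1.35 (99th; SE). The RAB16A call ended with robust dispersion estimates, with a filter at a mean of 5 CPM and after lowering by the 99th percentile, the last with a log2 fold change of 5.54.

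In emf2b, 3 stress and defence genes rose while a small heat shock gene fell. WRKY45, a transcription factor gene of salicylic acid-dependent defence, rose from 0.80 ± 0.48 CPM in WT to 12.9 ± 1.35 CPM in emf2b (SD, n = 2 each; log2 fold change 3.999 ± 0.44 SE, edgeR adjusted p = 0.00650). PBZ1, for a pathogenesis-related protein, rose from 4.07 ± 0.99 to 60.2 ± 35.7 CPM (3.85 ± 0.44, edgeR adjusted p = 0.00684). SNAC2, a stress-induced NAC gene, rose to 375 CPM in emf2b GAGT and 49.1 CPM in emf2b TTAG, from 17.8 and 22.8 CPM in WT (3.37 ± 0.81, edgeR adjusted p = 0.0316). HSP16.9A fell from 12316 ± 4710 to 2161 ± 481 CPM (-2.55 ± 0.41, edgeR adjusted p = 0.0117), with 15647 CPM in WT ACCC and 8986 CPM in WT CGTA; its reads could be shared with neighbouring HSP16.9 copies. Of 8 tested stress and defence genes, 3 rose, 1 fell and 4 did not pass the test; adjusted over the list alone, 4 rose and 1 fell, and DESeq2 called 3 higher and 2 lower of 11. The camera adjusted p was 0.658 and the median was 1.24, but 0.55 without emf2b GAGT, 2.15 without WT ACCC and -0.13 over the 7 members with a mean of 5 CPM or more. The SNAC2 call ended with DESeq2, with robust dispersion estimates, with both higher count filters and after lowering of emf2b counts (log2 fold change 3.51 at the 99th percentile), and the HSP16.9A call ended with a filter at a mean of 5 CPM.

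Of 16 tested photosynthesis genes, GLO1, for glycolate oxidase, was the only call. It rose from 0.45 ± 0.30 to 6.70 ± 3.90 CPM (SD, n = 2 each; log2 fold change 3.82 ± 0.62 SE, edgeR adjusted p = 0.0118). The list had 1 higher and 0 lower when adjusted over the list alone, a median of 0.43 (0.24 to 0.56 with 1 library left out) and a camera adjusted p of 0.299. Among the 5 reference genes, UBQ10, a polyubiquitin gene, rose from 181 ± 45.0 to 645 ± 199.9 CPM (1.80 ± 0.30, edgeR adjusted p = 0.0120), and the other 4 did not pass the test, with 1 higher and 0 lower when adjusted over the list alone. Their set did not pass camera (adjusted p = 0.658, direction down); its median was -0.27 (-0.45 to -0.11 with 1 library left out) and its mean 0.14. The GLO1 call ended after lowering of emf2b counts by the 99th percentile, at a log2 fold change of 3.77 (edgeR adjusted p = 0.0506), and the UBQ10 call with a filter at a mean of 5 CPM.

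**Figure D2:**
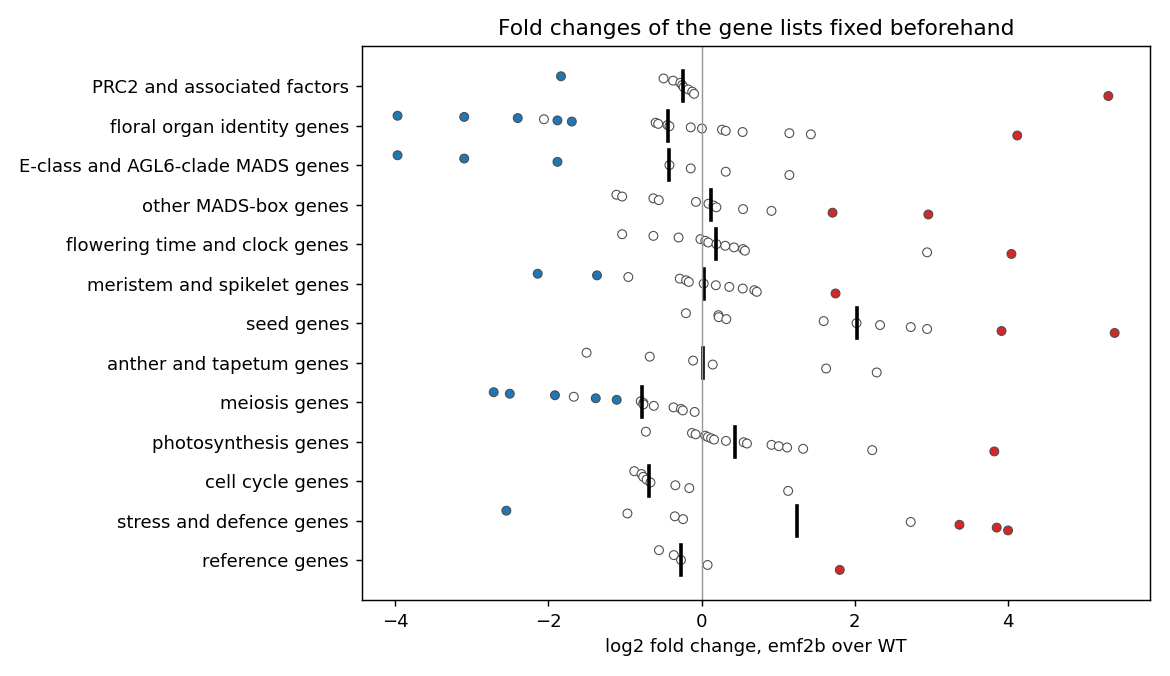
Log2 fold change (emf2b over WT, horizontal axis) of each tested member of the 13 gene lists; filled circles passed the edgeR test at an adjusted p under 0.05 (red higher, blue lower), open circles did not, and the vertical bars are list medians. All 14 meiosis genes lie below 0 (median -0.78), and the seed genes have the highest median, 2.02, which was 0.34 with the stricter filter.

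Over the whole transcriptome, weakly expressed loci made up most of the calls. Of 22615 loci tested, 3057 rose and 499 fell in emf2b, so 86.0% of the 3556 calls were upward. The median log2 fold change of all tested loci, called or not, was 0.01. It was 0.94 in the lowest tertile of mean expression, -0.08 in the middle and -0.13 in the highest. By mean expression over the 4 libraries, the lowest tertile of the tested loci held 2316 of the higher calls (75.8%) and 36 of the lower calls. The highest tertile held 240 higher and 290 lower calls, which is 58.1% of the lower ones. Higher calls had a median of 0.15 CPM in WT and 2.25 CPM in emf2b. Lower calls had medians of 37.9 and 17.4 CPM. The loci with the widest upward change were LOC_Os04g07850 (chromosome 4), with 11 reads in emf2b GAGT, 77 in TTAG and 0 in WT, and LOC_Os02g18920 (chromosome 2), with 34, 42 and 0. Against a floor of 3 reads over the group these were at least 56.5-fold (16.3-fold from GAGT alone) and at least 48.8-fold higher. Downward they were LOC_Os03g46300 (chromosome 3), with 55 reads in WT and 0 in emf2b, at least 9.53-fold lower, and LOC_Os03g44950 (chromosome 3), with 23 reads in WT ACCC, 106 in CGTA and 2 in emf2b, a depth-adjusted ratio of 33.5 with a 95% exact interval of 9.09 to 279.7 (13.5 from ACCC alone). All 4 calls ended without either WT library, those of LOC_Os04g07850 and LOC_Os03g46300 also after thinning, that of LOC_Os03g46300 without emf2b TTAG and that of LOC_Os03g44950 without either emf2b library. Lowering of emf2b counts by the 99th percentile ended all 4, with upward log2 fold changes then at 8.41 and 8.12.

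The emf2b libraries held reads at more loci than the WT libraries despite their lower depth. At 12932305 reads each, 35614 and 39673 loci had a read in emf2b GAGT and TTAG, and 28713 and 27193 in WT ACCC and CGTA. At the 9379 loci with no WT read, emf2b GAGT had a total of 899 and TTAG 1750 CPM. These loci include 150 of the higher calls, so their reads need not be background alone. When each emf2b library was lowered by the 99th percentile of its counts at those loci, 494 higher and 64 lower calls were found, 3 of the lower ones new. The lowering removed 83.8% of the 3057 higher and 87.8% of the 499 lower calls, so a call that it ended was not by that alone one made of background. Without WT ACCC 9 loci passed the edgeR test, and without WT CGTA 0 did (5415 and 4333 at an unadjusted p under 0.05). Nothing in the labels says that libraries of 1 group came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

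**Figure D3:**
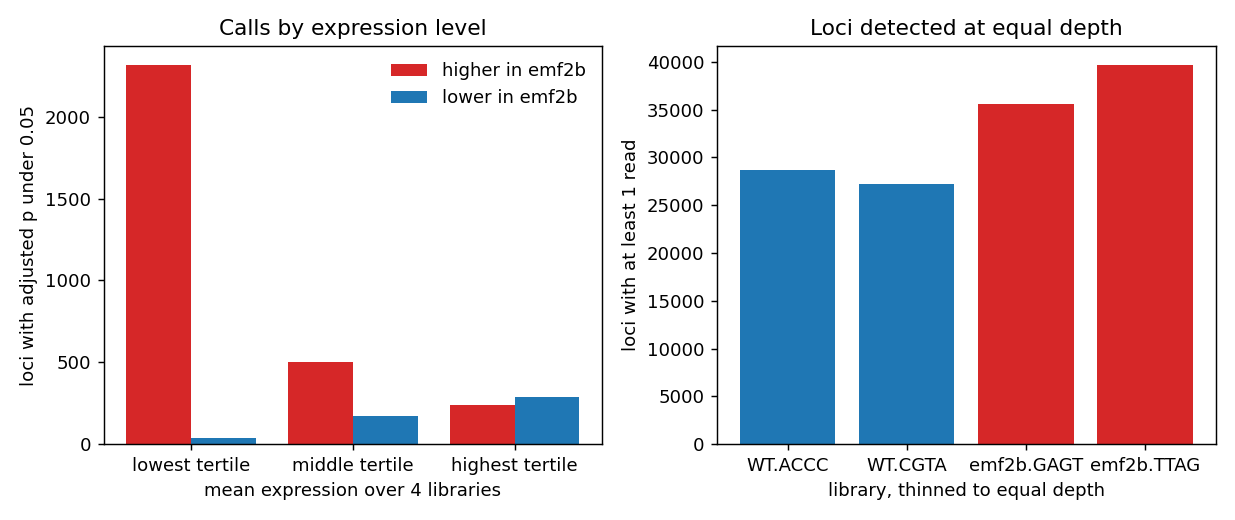
Left, number of loci with an edgeR adjusted p under 0.05 (vertical axis) in each tertile of mean expression over the 4 libraries, with higher calls in red and lower calls in blue; the lowest tertile holds 2316 higher and 36 lower calls. Right, loci with at least 1 read (vertical axis) in each library after thinning to 12932305 reads; the emf2b libraries reach 35614 and 39673, and the WT libraries 28713 and 27193.

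Calls were spread over all 12 chromosomes with unequal shares. On chromosome 11, 22.2% of the tested loci were called, against 15.3% elsewhere (odds ratio 1.57, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.09e-09 over 12 chromosomes). Chromosomes 10 and 12 also had a higher share, and chromosomes 1, 2 and 3 a lower one, at an adjusted p under 0.05. On chromosome 9, which carries EMF2B, 17.8% of the tested loci were called against 15.6% elsewhere (adjusted p = 0.0640). Loci on a chromosome are not independent replicates, and no chromosome passed with DESeq2 calls or without the low-count filter.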

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

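The filter at a mean of 5 CPM, the thinning and both ways of lowering emf2b counts were chosen after the result was seen. The count of 3556 calls (3057 higher, 499 lower; 304 lower at least 2-fold) stayed within 1.5 times in total under RLE factors, library totals, DESeq2 (3554, with 2890 loci shared), no filter, legacy and robust dispersions, both other thresholds and thinning (2545). It was 1412 (1217 higher, 195 lower) with the stricter filter, 210 (183 and 27) at a mean of 5 CPM, 1392 (1187 and 205) after lowering by the 95th percentile and 558 (494 and 64) by the 99th. All 1412 and all 210 were among the 3556, and fewer loci were tested (18906 and 13761). The filter at a mean of 5 CPM also ended calls of loci that stayed in the test, such as HSP16.9A and UBQ10. Of the 499 lower calls, 463 had a WT mean over 5 CPM, yet 27 lower calls were left by that filter. The Benjamini-Hochberg cutoff of unadjusted p was looser with 3556 calls of 22615 loci than with 210 of 13761. Calls of well-counted loci can thus depend on the many weakly expressed higher calls. How much of the loss this explains was not tested. Leaving out 1 library gave 0 to 2988 calls (0 to 2782 higher, 0 to 550 lower): 2988 without emf2b GAGT (206 lower), 2879 without emf2b TTAG, 9 without WT ACCC and 0 without WT CGTA (edgeR; 4333 at an unadjusted p under 0.05; DESeq2 was not run without a library). A group left with 1 library is assumed to vary like the other, and 1 residual degree of freedom then remains. The log2 fold change of EMF2B was -1.95 to -1.73 with a library left out (edgeR adjusted p up to 0.121) and -1.96 to -1.72 under all 15 alternatives, and it passed except without either WT library. The 27 calls on the lists became 17 with the stricter filter, 9 at a mean of 5 CPM, 17 and 13 after lowering by the 95th and 99th percentile, and 0 to 33 with a library left out. The 2 lists passing camera became 0 with an estimated correlation, 0 with fry (smallest adjusted p 0.0985), 4 after thinning, 1 after either lowering, and 1 to 5 with a library left out. The 6 chromosomes became 0 with DESeq2, 0 without the filter, 1 with the stricter filter, 0 at a mean of 5 CPM, 1 and 2 after lowering by the 95th and 99th percentile, and 0 to 6 with a library left out. The lowest tertile held 75.8% of the higher calls, but 0% at a mean of 5 CPM, a filter that removes that tertile, 35.2% after lowering by the 99th percentile, and 0 to 76.6% with a library left out; without WT CGTA no higher call was left to divide. Of 783 values of the 54 named genes under these alternatives, 654 kept their side of the threshold, 123 kept direction but not the call, and 5 gained a call. The 654 include changes of sign in genes called in neither setting, such as KRP1 (1.13, lowest -1.13) and OsMADS3 (-0.60, highest 0.19). Of the called genes 1 reversed: FIE1 had -1.98 ± 3.75 (SE) after lowering by the 99th percentile (edgeR adjusted p = 0.782), with almost none of its reads left. EMF2B, MEL1, OsMADS1, OsMADS8, PBZ1, SL1, WRKY45 and ZEP1 lost their calls only without a WT library, and OsMADS6 only without WT CGTA. In simulation at these library sizes, with 2 libraries per group and 200 loci changed, 6% of 2-fold changes were called, and depth was not varied. With 3556 real calls the cutoff of unadjusted p was looser, so that share need not hold for the real comparison. No paired analysis was possible because the columns carry barcodes and no replicate numbers, so the planned fit with a replicate block was not run.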

Other observations

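The YABBY, heat shock and dehydrin lists and their members were chosen after the values were seen, as were the depth test, the test on the ratio of the emf2b libraries, and the tests on dehydrin and meiosis genes; for both tests that lowered emf2b counts the outcome that would decide was written down first. YABBY genes, the family of DL and OsYABBY3, included 4 that fell in emf2b. OsYABBY1 fell from 27.4 ± 15.5 CPM in WT to 2.34 ± 0.36 CPM in emf2b (SD, n = 2 each; log2 fold change -3.57 ± 0.46 SE, edgeR adjusted p = 0.00759), and OsYABBY4 from 73.9 ± 21.6 to 28.5 ± 2.47 CPM (-1.41 ± 0.23, edgeR adjusted p = 0.0122). With OsYABBY3 and DL, 4 of the 8 tested members fell and 0 rose. The list had a median of -1.39, and no set test is given for lists chosen in this way. OsYABBY7 stood at 25.1 ± 1.92 CPM in WT and 26.4 ± 4.57 CPM in emf2b. Without WT CGTA the median was -0.88 and 0 members passed edgeR's test, 1 passed without WT ACCC and 2 without emf2b GAGT; the OsYABBY4 call also ended without WT ACCC and at a mean of 5 CPM.

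Heat shock genes differed within WT. HSP101 had 1485 CPM in WT ACCC and 393 in WT CGTA, and 491 and 1161 CPM in emf2b GAGT and TTAG. HSP18.0 had 10301 and 2442 CPM in WT, and 2766 and 6914 in emf2b. All 9 tested heat shock genes had negative log2 fold changes (median -0.74) and 1, HSP16.9A, fell. The median was -0.0043 without WT ACCC and -1.44 without WT CGTA.

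Most loci called higher in emf2b were weakly expressed. Sequencing depth is argued against as the source of the added loci with reads. At equal depth the lower emf2b library had reads at 1.24 times as many loci as the higher WT library. That outcome followed from the unthinned counts, in which the shallower emf2b libraries already had reads at more loci. After thinning, 2190 higher and 355 lower calls were found. Diffuse background reads as the whole cause of the higher calls could be judged only at the level subtracted. After lowering by the 99th percentile at loci with no WT read, 118 of the 240 higher calls of the highest tertile still passed. That lowering is small at well-counted loci by construction, so their passing shows only that a background of that size does not make up these 118 calls. The median log2 fold change of the 240 was 1.61 against 1.47 before. The lower calls of this tertile shifted upward as well (-0.82 against -0.95), so the rise decides nothing. A background above that level was not tested. For the 2316 higher calls of the lowest tertile, background may account for an unknown share. The lowering removed 92.5% of them, past the mark written down first for background, and their median log2 fold change went from 4.03 to 2.50. It also removed 83.3% of the 36 lower calls of that tertile and 87.8% of all lower calls. The 7.72 higher calls then left per lower call passed the mark written down against background as the whole cause. Since calls of both directions were lost, neither outcome decides anything. The log2 ratio of TTAG to GAGT reads, scaled by library total and TMM factor, was 0.979 over uncalled loci with no WT read. It was -0.165 and -0.473 over higher calls of the middle and highest tertile. Over the 2316 loci it was 0.515, between these values. Background and release of loci from Polycomb repression, which the genotype would give and which no value here tests, cannot be told apart for these loci.

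Dehydrin and ABA-response genes had more reads in emf2b, mostly in GAGT. RAB16B had 170.3 CPM in GAGT and 14.8 in TTAG, against 1.02 and 2.43 in WT, and LIP9 had 7368 and 562 against 453 and 492. Of 8 tested members 4 rose and 0 fell (median 3.21); 7 were higher without TTAG (median 4.07) and 0 passed edgeR's test without either WT library. A water or handling stress of the GAGT panicles could account for part of this, but without GAGT the median was still 1.63, with 4 members higher, between the values that would have decided either way. An effect of the genotype and a difference of 1 library cannot be told apart with 2 emf2b libraries.

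The 14 meiosis genes all had negative log2 fold changes in emf2b. Younger mutant panicles may account for this within the sampled length range, and meristem and spikelet genes, which might then be higher as a set, gave no decision (camera across all tested genes, unadjusted p = 0.338, direction down). Fewer dividing cells may be another cause. The cell cycle list was lower by camera across all tested genes at an unadjusted p of 0.0279 (adjusted 0.0726). With an estimated correlation camera gave an unadjusted p of 0.440. The median of the cell cycle list, -0.692 (-0.97 to -0.42 with 1 library left out), did not reach the -0.776 of the meiosis list (-1.34 to -0.70). Stage, cell composition and genotype cannot be told apart here, since no label gives the length of the panicles in each library. The same limit holds for the floral organ identity and YABBY genes that fell.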
